A study of Homo sapiens with 8 samples.

How the data were processed

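RNA was measured in CCD-1077Sk cells, a human skin fibroblast line, collected 6 h after treatment. Per the labels' protocols, RNA was extracted with TRIzol and libraries were prepared from total RNA with a VAHTS Total RNA-seq kit. The 8 libraries fall into 4 groups of 2: control (vehicle), transforming growth factor beta 1 (TGFB1) with DMSO, celastrol at 500 nM, and TGFB1 with celastrol at 500 nM. Replicate numbers are those of the sample titles; for celastrol replicate 2 another label gives the number 3. The dose of TGFB1 is not given in the sources used here. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

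The deposited table holds 1 normalized signal value per gene and library for 24598 genes. Per the submitters' processing notes, Partek 10.0.22, STAR 2.7.3a and DESeq2 were used with build hg38; their roles, the annotation release, the counting rule, its use of strand and the low-count filter are not given in the sources used here. The values themselves show what the unit is. In each library the median ratio to the geometric mean, over the 20682 genes above 0 in all libraries, was 1.0077, as left by dividing each library by 1 size factor. Between 73.8% and 75.8% of values in a library were whole multiples of a fixed step, within 0.02 reads, and the rest were fractional, as when reads are shared among genes. The deposited signal is therefore read as estimated reads divided by a size factor, scaled neither to a common total nor by length, and is called normalized reads here. The largest value of every gene was at least 11 estimated reads, so genes below that are not in the table.

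The step gives the depth. Estimated reads assigned to genes were 20716707 and 42518358 in the control libraries, 21161872 and 24602659 with TGFB1, 34879794 and 22615137 with celastrol, and 38583027 and 24406817 with TGFB1 and celastrol. A count of 0 allows up to 3 reads, which is between 1.8 and 4.24 normalized reads per library. This limit covers counting error only, since reads without molecular identifiers are not independent molecules. Because whole reads were not recovered for nearly all values, no count model was fitted.

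Values were analysed as log2(value + 1), which draws the log2 fold change of a low gene toward 0. Where 1 library of a group is at 0 and the other is not, the log2 fold change can instead exceed that between group means. Genes with at least 10 normalized reads in at least 2 libraries were tested, which left 22866. A linear model with 1 mean per group was fitted to all 8 libraries with limma 3.58.1 in R 4.3.3, with a trend of variance on mean, 4 residual degrees of freedom and two-sided tests. P-values were adjusted by the Benjamini-Hochberg method within each of 5 comparisons, with calls at 0.05: TGFB1 against control, celastrol with TGFB1 (against TGFB1), celastrol without TGFB1 (against control), TGFB1 with celastrol (against celastrol), and the interaction, which tests whether the celastrol difference depends on TGFB1. All adjusted p-values for genes are from this limma fit.

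The 23 gene lists, with 467 entries, were fixed before the data were examined, as were the tests, the rule for named genes and most alternatives. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison. Camera compares a list with the other genes, while the rotation test fry, used as an alternative, tests it against no change. With a correlation estimated per list, no list passed the threshold after adjustment in any of the 5 comparisons, so each camera call below depends on the preset correlation. The lists covered TGFB early response, collagen and matrix, contractile and myofibroblast, YAP and TAZ targets, matrix proteases, heat shock response, NRF2 targets, ATF4 and integrated stress response, endoplasmic reticulum chaperones, proteasome subunits, NF-kB and inflammatory, immediate early genes, cell cycle, cholesterol synthesis, interferon response, p53 targets, metallothioneins, fibroblast identity, markers of keratinocytes, endothelial cells, melanocytes and immune cells, and mitochondrially encoded genes.

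Named genes were those past the threshold with both libraries of a group above both of the other and at least 50 normalized reads in the higher group. Left out were names of clones, of LINC and LOC genes, of small RNAs and their host genes, and of pseudogenes. Names of antisense, overlapping, intronic and divergent transcripts were also left out. Rankings of rises and falls below are among the genes this rule allows. The 10 largest rises and falls were taken for TGFB1 and for celastrol with TGFB1, and 5 of each elsewhere. Up to 4 members with the smallest p per list, and 20 genes fixed in advance, could be added whatever their result, and the text names those needed to describe a list. Not every gene that the rule selects is named. Levels of genes linked to sex were left out of the named genes.

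The fit was tested on simulated reads for TGFB1 against control with 200 changed genes among 18930 tested. It called 56% of genes changed 1.5-fold, 76% of those changed 2-fold and 100% of those changed 4-fold or 8-fold, with 9 unchanged genes among 175 calls. All other simulated genes kept the control mean in every group, whereas 5364 of 22866 genes were called for TGFB1 in the data. These shares therefore check the fit and do not give its sensitivity in the data. Alternatives covered the pseudocount, filter, scaling, variance model, libraries in the fit, a replicate block, a fold threshold and leaving out each library. Weights from voom and the 3 scalings of the slope were added after the data were examined. The limits used for genes near 0 in the last section were also chosen after that, and a limit of 500 for an expressed neighbour was tried first. Gene positions are those of the deposited table, on hg38. Figures and the tests of the last section were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Exon lengths and overlaps came from GENCODE v29, which may not be the annotation the authors used. Overlaps of ATF7-NPFF, CCN1 and CCN2 were not checked, because these names were not found in it.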

Results

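Gene expression was measured in human skin fibroblasts (the CCD-1077Sk line) after 6 h with vehicle, with TGFB1, a cytokine that drives matrix production in fibroblasts, with celastrol, a plant triterpenoid, at 500 nM, or with both. The design addresses how celastrol alters gene expression mediated by TGFB1. Each group had 2 libraries with 20716707 to 42518358 estimated reads. In a principal component analysis, 86.5% of the variance lay along an axis that separated the 4 celastrol libraries from the other 4, and 8.5% along one that separated TGFB1 from control among the libraries without celastrol. Values below are normalized reads as mean ± SD with n = 2 libraries, and changes are log2 fold changes.

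The first comparison asked what TGFB1 did on its own. TGFB1 raised the fibrosis-associated gene CCN2, which encodes connective tissue growth factor. CCN2 (chromosome 6, 131948176 to 131951372) went from 22206 ± 583.2 to 150480 ± 10420, a log2 change of 2.76 (SE 0.10, adjusted p = 9.39e-07). The cytokines IL11 and LIF rose by 4.44 and 5.29, NOX4, an NADPH oxidase, by 2.53, and IL6 by 2.05. Among the largest rises were EGR2 (7.98), COMP (5.94), ANGPTL4, LIF, GPRIN3, TNFSF15, ST6GAL2, IL11 and HBEGF. The largest falls were in KIT, a receptor tyrosine kinase (-4.22), ARHGAP28, EVI2A, the matrix protease ADAMTS1 (-3.08), CSRNP3, RNF144B, FLRT3, KCNN2, PTX3 and RAB7B. EVI2A overlaps exons of NF1, LIF of LIF-AS1, ANGPTL4 of RAB11B-AS1, PTX3 of VEPH1, IL6 of STEAP1B, and ARHGAP28 and KCNN2 of genes with clone names, so their reads could have been split or exchanged. With only the 4 compared libraries in the fit, the calls of GPRIN3, NOX4, EVI2A, CSRNP3 and PTX3 were lost (adjusted p = 0.0655, 0.0607, 0.0605, 0.0723 and 0.0622).

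Of 31 measured genes of the TGFB early response, 22 were higher and 5 lower (23 and 5 adjusted over the list alone, camera adjusted p = 1.2e-11, adjusted p = 0.11 with an estimated correlation). PMEPA1 rose by 4.25 and JUNB by 3.64, while the inhibitory SMAD6 fell by 2.46. Of 36 collagen and matrix genes, 25 were higher and 0 lower (26 and 1 adjusted over the list alone, camera adjusted p = 2.4e-13, adjusted p = 0.21 with an estimated correlation). ELN, which encodes elastin, rose by 3.24, COL7A1 by 1.90 and FN1, fibronectin, by 1.38. COL1A1 rose by 0.70 (SE 0.15, adjusted p = 0.0116), a call lost without control replicate 1 or 2 (adjusted p = 0.0548 and 0.0518), without a variance trend (0.0572) and with only the 4 compared libraries (0.234). With these 4 the FN1 call was also lost (adjusted p = 0.129). COL1A2 (0.15), COL3A1 (-0.07), the smooth muscle actin gene ACTA2 (0.41) and POSTN (0.47) did not pass the threshold. With a replicate block, ACTA2 (adjusted p = 0.019) and POSTN (0.00374) passed; the replicate numbers are not established as pairs.

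Of 25 contractile and myofibroblast genes, 15 were higher and 0 lower (19 and 0 adjusted over the list alone, camera adjusted p = 1.4e-07, adjusted p = 0.34 with an estimated correlation), with TPM1 up by 1.20. YAP and TAZ targets had 13 of 22 higher and 2 lower (15 and 2 adjusted over the list alone, camera adjusted p = 2.5e-06, adjusted p = 0.11 with an estimated correlation). In that list CCN1 rose by 0.79, and ANKRD1 rose by 1.44 (adjusted p = 0.151 with only the 4 compared libraries). YAP1, which is not in the list, did not pass (0.06). Endoplasmic reticulum chaperones had 17 of 20 higher and 0 lower (19 and 0 adjusted over the list alone, camera adjusted p = 2.5e-11, adjusted p = 0.11 with an estimated correlation), and DNAJB9 was among the genes that rose; with a common total 9 were higher. Immediate early genes had 14 of 24 higher and 4 lower (14 and 4 adjusted over the list alone, camera adjusted p = 1.2e-05, adjusted p = 0.26 with an estimated correlation). Proteasome subunits had 7 of 31 higher and 0 lower (10 and 0 adjusted over the list alone, camera adjusted p = 1.4e-05, adjusted p = 0.21 with an estimated correlation), but their median of 0.16 became -0.06 with a common total, which left 1 higher and ended the list call (0.68), and median centring gave 25 higher. The metallothionein list, measured by 3 metallothioneins and the zinc transporter SLC30A1, had 3 of 4 higher and 0 lower (3 and 0 adjusted over the list alone, camera adjusted p = 0.00048, adjusted p = 0.24 with an estimated correlation), with MT2A up by 1.43 and SLC30A1 (0.15) not called; the metallothioneins have close copies and their reads are uncertain.

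Interferon response genes had 1 of 20 higher and 5 lower (1 and 5 adjusted over the list alone, camera adjusted p = 0.012, adjusted p = 0.26 with an estimated correlation), with IFIT2 down by 2.45 on the log2 scale; the list call was lost without control replicate 1 (0.068), and 9 were lower with a common total. The heat shock list had 12 of 28 higher and 3 lower (16 and 4 adjusted over the list alone, camera adjusted p = 0.047, adjusted p = 0.73 with an estimated correlation), and that call was lost without control replicate 1, TGFB replicate 1 or TGFB replicate 2 (0.13, 0.057 and 0.15), with a common total (0.37, 2 higher and 8 lower) and with the rotation test fry (0.13). Lists that did not pass camera were matrix proteases (4 higher and 3 lower of 13), NRF2 targets (7 and 2 of 27), ATF4 and integrated stress response (4 and 1 of 22), NF-kB and inflammatory (9 and 5 of 22), cell cycle (0 and 0 of 28), cholesterol synthesis (5 and 2 of 20), p53 targets (4 and 6 of 20) and fibroblast identity (3 and 1 of 14). Adjusted over the list alone, these counts were the same except for NF-kB and inflammatory (10 and 7), p53 targets (4 and 7) and fibroblast identity (3 and 2). A common total gave 8 cell cycle genes lower, 10 p53 targets and 7 cholesterol genes lower, with 0, 2 and 2 higher. The cell cycle list passed camera downward with a replicate block (0.022), with a common total (0.021) and without control replicate 2, TGFB replicate 1, celastrol replicate 1 or celastrol replicate 2 (0.026, 0.013, 0.0084 and 0.0083). NRF2 targets passed upward without control replicate 2 (0.047) or TGFB replicate 1 (0.018), and the ATF4 list without TGFB replicate 1 (0.028). The NF-kB list had a median of -0.14 while camera put it upward (adjusted p = 0.24, 0.031 with a common total), and PTGS2 was among the genes that rose. Tested against no change, fry also put it upward (adjusted p = 0.00038). HMOX1 rose by 0.62 and ATF3 by 0.61, while HSPA1A (-0.16), DNAJB1 (-0.17) and DDIT3 (-0.14) did not pass; HSPA1A and DNAJB1 were lower with a common total (adjusted p = 0.0258 and 0.00985). SMAD7 rose by 1.71 (adjusted p = 0.0571 with only the 4 compared libraries). The HMOX1 call was lost without control replicate 1 (adjusted p = 0.0627), without a variance trend (0.061) and with only the 4 compared libraries (0.173). The ATF3 call was lost without control replicate 1 or 2 (adjusted p = 0.0606 and 0.0609), with a common total (0.0624), without a trend (0.0581), with voom weights (0.0575) and with only the 4 compared libraries (0.207). Markers of keratinocytes (1 of 5 higher), endothelial cells (0 of 5), melanocytes (1 of 4 lower) and immune cells (1 of 5 higher) did not pass camera. The 13 mitochondrial transcripts (0 called) did not pass either. Counts adjusted over the list alone were the same for these 5 lists. With fry, keratinocyte (0.0017) and immune (0.03) markers passed upward and melanocyte markers downward (0.00092). The mitochondrial list passed camera upward without TGFB replicate 2.

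In all, 2937 genes were higher and 2427 lower with TGFB1 (limma, adjusted p under 0.05). Scaling to a common total gave 1417 higher and 5398 lower, with the median of all genes shifted by -0.21, and median centring gave 4778 and 1775, shifted by 0.12. The total of 5364 genes changed by TGFB1 was 3311 without control replicate 1, 3248 without control replicate 2 and 1684 when only the 4 compared libraries were fitted.

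**Figure D1:**
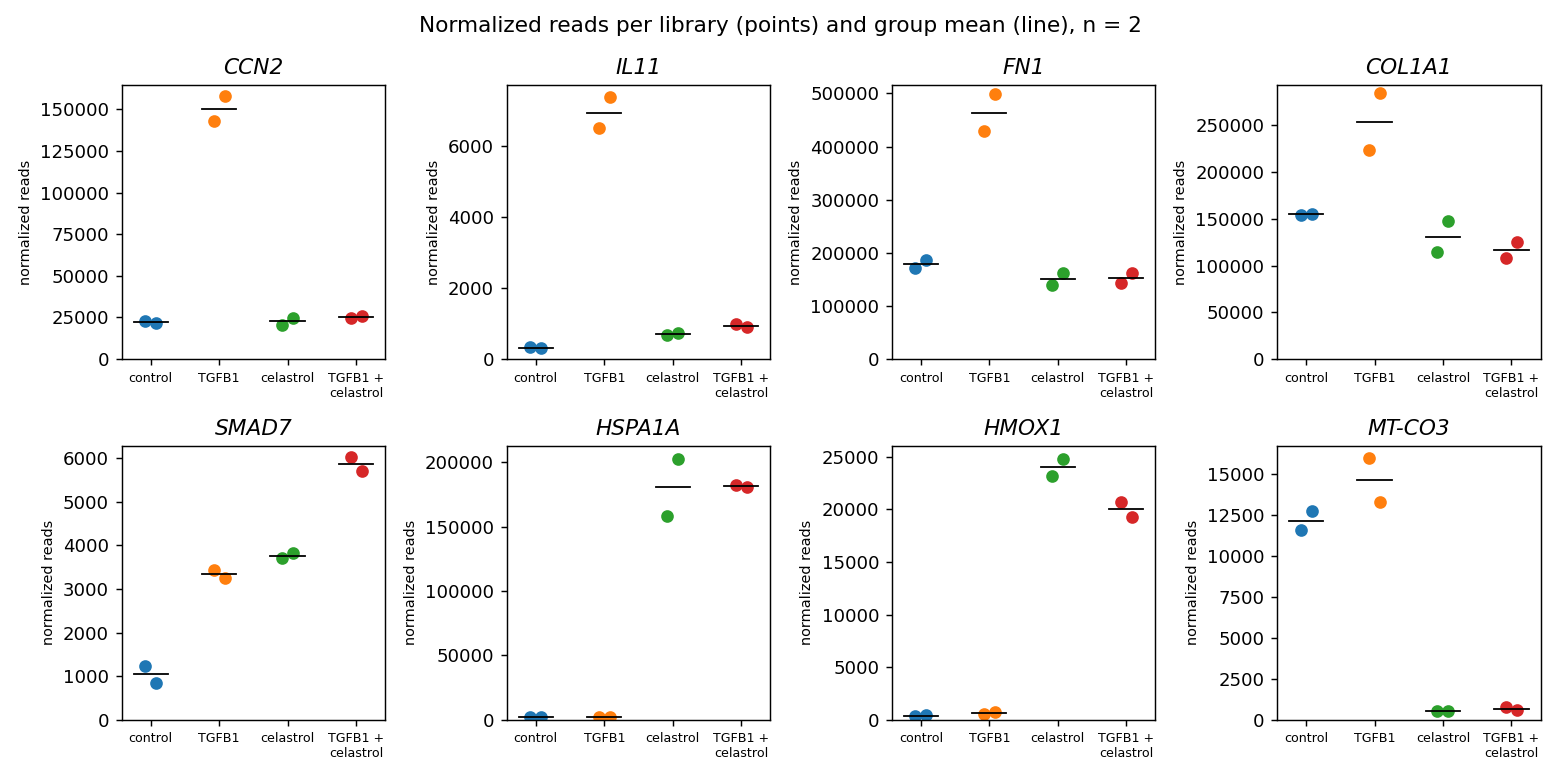
Normalized reads (vertical axis, linear from 0) of 8 genes in each of the 8 libraries (points), with the group mean (line), n = 2 per group. CCN2, IL11 and FN1 are highest with TGFB1 alone, while HSPA1A and HMOX1 are high and MT-CO3 is low in both celastrol groups.

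The second comparison, celastrol with TGFB1 against TGFB1 alone, is the one the design names. With celastrol, CCN2 was 25274 ± 1116, lower by -2.57 (SE 0.10, adjusted p = 3.96e-07). IL11 fell by 2.88 to 943.65 ± 72.32, LIF fell by 3.86, NOX4 fell by 2.94, FN1 fell by 1.60, COL1A1 fell by 1.11, COL1A2 fell by 0.63 and IL6 fell by 1.23. The largest falls were MT-CO3 (-4.48), ELN (-4.37), ESM1 (-4.21), COMP, IFNE, MT-ND6, LIF, TAS2R46, S1PR5 and SEMA7A. COL3A1 (-0.20), ACTA2 (-0.72), POSTN (-0.56), CCN1 (-0.02) and YAP1 (-0.02) did not pass. With a replicate block, COL3A1 (adjusted p = 0.00451), ACTA2 (0.000269) and POSTN (0.000372) passed, and with median centring COL3A1 (0.00268), ACTA2 (0.0444), CCN1 (0.0105) and YAP1 (0.00113) were lower.

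Genes of the heat shock response rose: 26 of 28 were higher and 1 lower (26 and 1 adjusted over the list alone, camera adjusted p = 3.5e-10, adjusted p = 0.27 with an estimated correlation). HSPA1A (chromosome 6, 31815543 to 31817946), an inducible HSP70 gene, went from 1954.4 ± 185.5 to 181510 ± 951.1, a change of 6.54 (SE 0.11, adjusted p = 1.64e-08). Its near-identical copy HSPA1B rose by 6.83, and reads of the pair could have been shared; the co-chaperone DNAJB1 rose by 5.16. HMOX1, heme oxygenase 1, rose by 5.03 and the stress transcription factor ATF3 by 4.28, while DDIT3 rose by 1.52, ANKRD1 by 2.39 and SMAD7 by 0.81. The largest rise was HSPA6 (chromosome 1, 161524540 to 161526894), another HSP70 gene, from 7.4303 ± 10.51 to 76904 ± 1235. Its SD with TGFB1 alone exceeded its mean, so the size of this rise is uncertain. HSPA6 has a close copy, HSPA7. The next among the genes that the rule allows were CD160, ARC, C9, BEND4, NEB, MOGAT2, ASB2, KCNN3 and MSTN. Of these, CD160, BEND4, MOGAT2, ASB2, KCNN3 and MSTN were at 0 in both TGFB1 libraries. Against a floor of 3 reads per library they were at least 125, 90.6, 75.8, 71.8, 61.6 and 60.1-fold higher. C9 overlaps exons of DAB2, NEB of RIF1, CD160 of RNF115, DNAJB1 of TECR, DDIT3 of MBD6, ELN of ELN-AS1, MT-CO3 of MT-ATP6, ACTA2 of FAS, and ASB2, ESM1 and YAP1 of genes with clone names.

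Collagen and matrix genes had 27 of 36 lower and 2 higher (28 and 2 adjusted over the list alone, camera adjusted p = 3.5e-10, adjusted p = 0.27 with an estimated correlation), with COL4A1 down by -2.33. Contractile and myofibroblast genes had 19 of 25 lower and 1 higher (camera adjusted p = 2.6e-06, adjusted p = 0.30 with an estimated correlation), with TPM1 at -1.71. Endoplasmic reticulum chaperones had 18 of 20 lower and 1 higher (camera adjusted p = 1.9e-06, adjusted p = 0.27 with an estimated correlation), and proteasome subunits had 21 of 31 lower and 0 higher (camera adjusted p = 1.5e-05, adjusted p = 0.27 with an estimated correlation). Both counts depended on the scaling: a common total gave 11 chaperones lower, and 8 proteasome subunits lower and 1 higher (median -0.08), while median centring gave 19 and 31 lower. All 13 mitochondrially encoded transcripts were lower, with a median of -2.17 (camera adjusted p = 3.5e-08, adjusted p = 0.27 with an estimated correlation); under 3 other scalings 12 or 13 of them were called lower. The 3 metallothioneins of the 4 genes in their list were lower (camera adjusted p = 0.015, adjusted p = 0.27 with an estimated correlation).

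Immediate early genes had 21 of 24 higher and 0 lower (camera adjusted p = 3.5e-08, adjusted p = 0.27 with an estimated correlation), with FOSB up by 5.38, EGR3 by 5.56 and NR4A1 by 4.74. The ATF4 and integrated stress response list had 19 of 22 higher and 0 lower (camera adjusted p = 3.7e-06, adjusted p = 0.27 with an estimated correlation), with PPP1R15A up by 3.27. Interferon response genes had 12 of 20 higher and 0 lower (camera adjusted p = 0.013, adjusted p = 0.27 with an estimated correlation), with IFIT2 up by 2.79. The TGFB early response list did not pass camera, with 15 members higher and 15 lower of 31. Among them PMEPA1 fell, and LIF, IL11 and CCN2 fell as given above, while BHLHE40 rose by 1.14, KLF10 by 1.49 and SNAI1 by 1.80. The other lists that did not pass were YAP and TAZ targets (7 higher and 9 lower of 22), matrix proteases (6 and 3 of 13), NRF2 targets (9 and 4 of 27), NF-kB and inflammatory (10 and 8 of 22), cell cycle (2 and 3 of 28), cholesterol synthesis (9 and 2 of 20), p53 targets (9 and 3 of 20) and fibroblast identity (2 and 4 of 14). The balance of some of these depended on the scaling. A common total gave 14 higher and 1 lower for cholesterol synthesis, 14 and 2 for p53 targets, 12 and 1 for NRF2 targets, 10 and 8 for YAP and TAZ targets and 6 and 2 for cell cycle. Median centring gave 3 and 7, 3 and 6, 8 and 8, 6 and 12, and 1 and 8 in the same order, and 2 and 8 for fibroblast identity. Markers of other cell types had 2 higher and 1 lower of 5 for keratinocytes and 3 of 5 higher for endothelial cells. Melanocytes had 3 of 4 higher and immune cells 4 of 5. None of these 4 lists passed camera, though the endothelial one did without control replicate 1 or 2 or TGFB replicate 1. With fry, which called 20 of the 23 lists here, keratinocyte markers passed downward (0.02). Endothelial (0.00026), melanocyte (0.00022) and immune (0.00026) markers passed upward. The table holds only genes that reach 11 estimated reads in some library. Markers near 0 without celastrol, such as PECAM1 (0 with TGFB1, 67.27 with both), entered it by rising, so such rises were fixed in advance. In all, 8564 genes were higher and 5933 lower. A common total gave 9810 and 4183, with the median of all genes shifted by 0.16, and median centring gave 6956 and 9094, shifted by -0.29. Among genes with a mean of at least 50, 4053 of 9344 calls were higher, so more were lower.

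**Figure D2:**
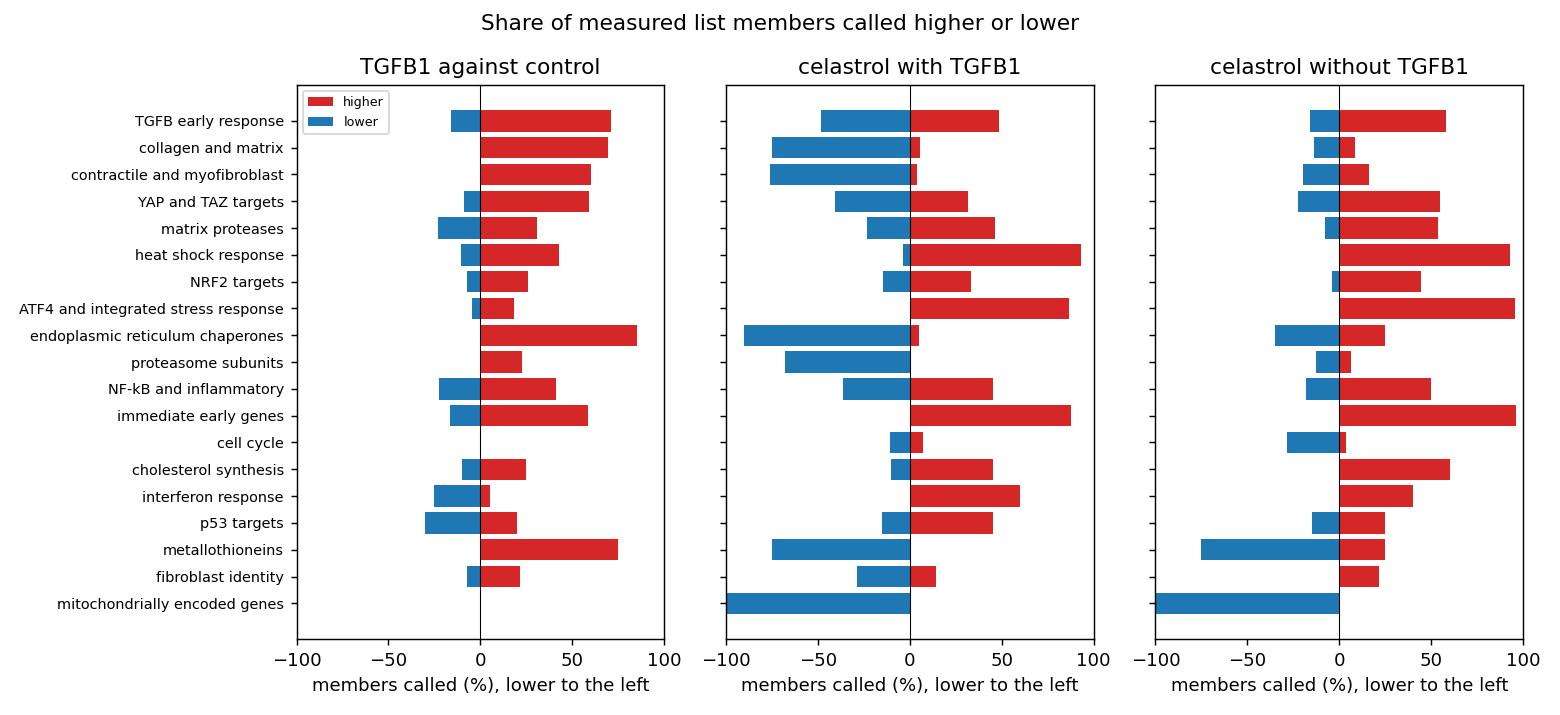
Share of the measured members of each gene list called higher (right, red) or lower (left, blue) in percent, for TGFB1 against control, celastrol with TGFB1 and celastrol without TGFB1, leaving out the lists of other cell types. Collagen and matrix genes are called higher with TGFB1 (25 of 36) and lower when celastrol is added (27 of 36).

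The third comparison, celastrol without TGFB1, also raised heat shock, ATF4 and immediate early genes, in cells given no TGFB1. HSPA1A was higher by 6.36 (SE 0.11, adjusted p = 1.69e-08), DNAJB1 by 5.11, HMOX1 by 5.91, ATF3 by 4.98, DDIT3 by 1.54 and ANKRD1 by 3.27. SMAD7 (1.88), CCN1 (0.64), IL11 (1.14) and IL6 (1.03) were also higher. CCN2 (0.03), NOX4 (-0.57), FN1 (-0.24), COL1A1 (-0.25), COL1A2 (-0.31), COL3A1 (-0.13), ACTA2 (-0.04), POSTN (-0.06) and YAP1 (0.09) did not pass. With a replicate block, NOX4 (adjusted p = 0.00418), FN1 (0.0053), COL1A1 (0.0288), COL1A2 (0.00233) and COL3A1 (0.0395) were lower. With median centring these 5 were also lower (0.0426, 0.0185, 0.0376, 0.0109 and 0.0324), and COL1A2 and FN1 were with a common total (0.0251 and 0.0443) and voom weights (0.0159 and 0.0309). The largest rises were HSPA6, NEB, XIRP1, C1orf87 and BEND4, and C1orf87, at 0 in both control libraries, was at least 109-fold higher. The largest falls were MT-CO3 (-4.51), CRYGS, ATF7-NPFF, MT-ND6 and TAS2R30. CRYGS overlaps exons of TBCCD1, while ATF7-NPFF was not found in the annotation used here, so its overlap was not checked. Across 22866 genes the celastrol changes with and without TGFB1, which share no library, had a Pearson r of 0.907 and a Spearman rho of 0.83. Genes are not independent replicates. Most genes near 0 without celastrol are in the table because they were higher with it, which favours such a correlation.

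Heat shock genes had 26 of 28 higher (27 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.4e-13, adjusted p = 0.40 with an estimated correlation), immediate early genes 23 of 24 (camera adjusted p = 9.1e-13, adjusted p = 0.40) and ATF4 and integrated stress response genes 21 of 22 (camera adjusted p = 3.1e-08, adjusted p = 0.40), with 0 lower in each over all genes. The 13 mitochondrial transcripts were lower (camera adjusted p = 4.6e-10, adjusted p = 0.40 with an estimated correlation). The TGFB early response list had 18 of 31 higher and 5 lower (camera adjusted p = 0.036, adjusted p = 0.49 with an estimated correlation), with BHLHE40 up by 3.66 and KLF10 by 3.24; the list call was lost without celastrol replicate 2 (0.067) and with a replicate block (0.064). Collagen and matrix genes had 3 of 36 higher and 5 lower (1 and 3 adjusted over the list alone, camera adjusted p = 0.044, adjusted p = 0.52 with an estimated correlation). This call was lost without control replicate 1, celastrol replicate 1 or TGFB1 with celastrol replicate 2, and with fry (0.25). The number lower depended on the scaling, with 14 for a common total, 10 for TMM and 21 for median centring. Cell cycle genes had 1 of 28 higher and 8 lower (1 and 5 adjusted over the list alone, camera adjusted p = 0.0015, adjusted p = 0.52 with an estimated correlation). This call was lost without celastrol replicate 2 and with fry (0.21), and median centring gave 17 lower. Cholesterol synthesis genes had 12 of 20 higher (camera adjusted p = 0.036, adjusted p = 0.51 with an estimated correlation), lost without control replicate 2 or celastrol replicate 1 (0.082 and 0.071) and with a common total (0.082). Endothelial (4 of 5 higher) and immune (3 of 5 higher) markers passed camera (adjusted p = 0.044 for both, adjusted p = 0.40 with an estimated correlation). Only 5 of 8 endothelial and 5 of 10 immune markers were tested. Markers near 0 without celastrol, such as CD163 (0 in control, 95.43 with celastrol), are in the table because they rose. For such markers a rise was fixed in advance. The endothelial call was lost without either celastrol library (0.062 and 0.06) or TGFB1 with celastrol replicate 2 (0.05), and the immune call without these (0.062, 0.071 and 0.05) or control replicate 1 (0.086). The lists that did not pass were contractile and myofibroblast (4 higher and 5 lower of 25), YAP and TAZ targets (12 and 5 of 22), matrix proteases (7 and 1 of 13), NRF2 targets (12 and 1 of 27), endoplasmic reticulum chaperones (5 and 7 of 20), proteasome subunits (2 and 4 of 31), NF-kB and inflammatory (11 and 4 of 22), interferon response (8 and 0 of 20), p53 targets (5 and 3 of 20), the metallothionein list (1 and 3 of 4), fibroblast identity (3 and 0 of 14), keratinocyte (2 and 0 of 5) and melanocyte (3 and 0 of 4) markers. Median centring gave 14 contractile genes, 15 chaperones and 20 proteasome subunits lower. Of these lists, NRF2 targets passed camera upward with a replicate block (0.027) and without control replicate 2 (0.018) or celastrol replicate 1 (0.021), proteasome subunits downward with a common total (0.015), and contractile genes downward without control replicate 2 (0.018). In all, 7737 genes were higher and 4868 lower. Median centring gave 6751 and 7470, with the median of all genes shifted by -0.17. Among genes with a mean of at least 50, 3761 of 7932 calls were higher, so more were lower.

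The fourth comparison asked what TGFB1 did in the presence of celastrol. CCN2 (0.16), IL11 (0.42), FN1 (0.02), COL1A1 (-0.16), SMAD7 (0.64) and HSPA1A (0.02) did not pass. Of 22866 genes, 1 was higher and 1 lower. An unadjusted limma p under 0.05 was found for 868, fewer than the 1143 that chance alone would give. The fit used 1 spread per gene for all groups. Log2 differences between replicates had a smaller SD in the celastrol groups (0.243 and 0.223) than in control and TGFB1 (0.287 and 0.345). P-values of this comparison may therefore be too large, which lowers that count. The gene that was higher was the immediate early gene FOSB (log2 change 1.04, adjusted p = 0.0499), and its call was lost without any 1 of the 8 libraries (adjusted p from 0.13 to 1), with TMM or median scaling (0.0525 and 0.0531) and without a trend (0.228). The lower one, named after its values were seen, was FOXD4L6 (adjusted p = 0.0499), at 15.643 ± 3.919 with celastrol and 0.062417 ± 0.06592 with both, one of a family of near-identical genes whose reads are uncertain; its call was also lost without any 1 of the 8 libraries, with TMM or median scaling, with a pseudocount of 10 (0.108) and with the 4 compared libraries (0.315). The TGFB early response list had 0 of 31 members called over all genes and 7 higher with 0 lower adjusted over the list alone (camera adjusted p = 1.4e-10, adjusted p = 0.29 with an estimated correlation, 0.31 with fry). These 7 were JUNB (0.62), PMEPA1 (0.61), SMAD7 (0.64), SKIL (0.44), BHLHE40 (0.40), IL11 (0.42) and KLF10 (0.41). Camera called 9 lists in this comparison, among them some without a member called over the list alone: cell cycle (adjusted p = 2.5e-09, upward), mitochondrial transcripts (1.8e-06, upward) and heat shock (2.2e-06, downward), with adjusted p = 0.57 for each with an estimated correlation. The camera result of the early response list is therefore not particular to it. The cell cycle result turned direction without celastrol replicate 2 (0.98), without which the heat shock call was also lost (0.51), and the mitochondrial call was lost without TGFB1 with celastrol replicate 1 (0.56).

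Across the 5364 genes called for TGFB1 against control, the slope of the change with celastrol on the change without it was 0.03, with a median ratio of 0.018. These changes share no library. Of these genes, 54.1% had the same sign in both. For the 1747 genes with at least a 2-fold change the slope was 0.035. It was 0.071 for the 2937 raised genes and -0.001 for the 2427 lowered ones.

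**Figure D3:**
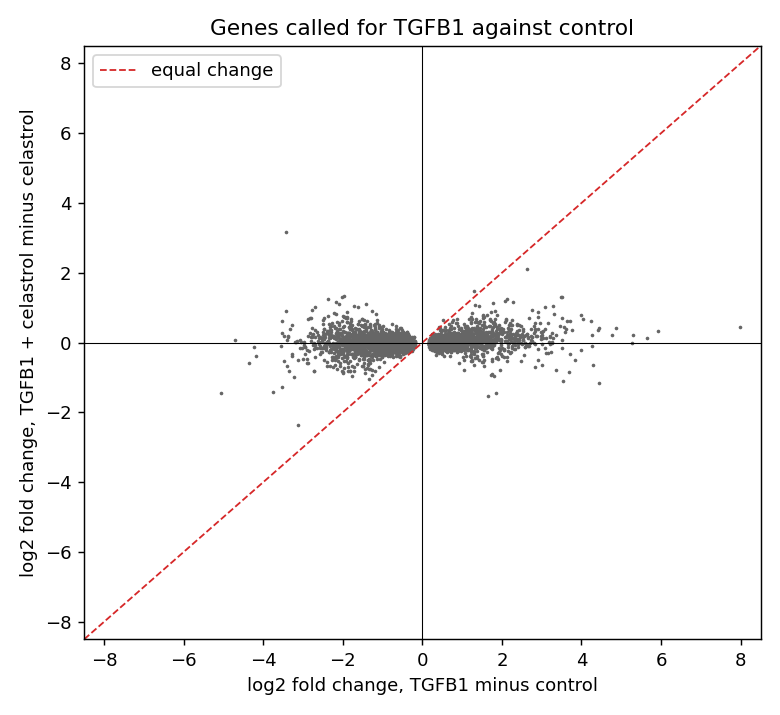
Log2 fold change of TGFB1 with celastrol against celastrol (vertical axis) by that of TGFB1 against control (horizontal axis) for the 5364 genes called for TGFB1 against control; the dashed line marks equal change. The points lie along the horizontal axis, with a slope of 0.03.

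The interaction tested the difference directly. It was lower in 1576 genes and higher in 997. CCN2 (-2.60, SE 0.14, adjusted p = 2.75e-05), IL11 (-4.02), FN1 (-1.36), IL6 (-2.26) and SMAD7 (-1.07) passed, as did HMOX1 (-0.89) and COL1A1 (-0.86, adjusted p = 0.0371). The COL1A1 call was lost without any library but TGFB1 replicate 1 and celastrol replicate 1. It was also lost with a common total (adjusted p = 0.0824), without a trend (0.128) and with a pseudocount of 0.1 (0.061). The SMAD7 call was lost without any 1 of the 4 celastrol libraries, and that of HMOX1 without any of these or control replicate 1; without a trend the SMAD7 and HMOX1 calls were lost (adjusted p = 0.0839 and 0.099). The total of 2573 genes with an interaction was 1624 and 1487 without control replicates 1 and 2, 1599 and 1313 without celastrol replicates 1 and 2, and 1397 and 1189 without TGFB1 with celastrol replicates 1 and 2. It was 1245 without a variance trend. A common total gave 2474 higher and 801 lower, with the median of all genes shifted by 0.22, and median centring gave 784 and 2748, shifted by -0.12.

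Most lists that moved with TGFB1 had a lower interaction. The TGFB1 and control libraries enter the interaction with the sign opposite to that in TGFB1 against control. For lists that rose with TGFB1, this favours a lower interaction without any effect, so these list results are not separate evidence. The TGFB early response had 20 of 31 lower and 4 higher (camera adjusted p = 9.6e-12, adjusted p = 0.11 with an estimated correlation). Contractile and myofibroblast genes had 11 of 25 lower (4.7e-08, 0.28 with an estimated correlation), YAP and TAZ targets 10 of 22 (2.8e-06, 0.11), endoplasmic reticulum chaperones 10 of 20 (4.7e-11, 0.11), and the metallothionein list 3 of 4 (0.00056, 0.22), with 0 higher in each as deposited. Adjusted over the list alone, these were 17, 12 with 2 higher, 14 and 3 lower, and the early response had 22 lower and 5 higher. Immediate early genes had 12 of 24 lower and 1 higher (13 and 3 adjusted over the list alone, camera adjusted p = 4.6e-06, 0.22 with an estimated correlation). Heat shock genes had 9 of 28 lower and 0 higher (16 and 1 adjusted over the list alone, camera adjusted p = 0.001, adjusted p = 0.51 with an estimated correlation), a call lost with fry (0.085). Proteasome subunits, with 1 of 31 lower (3.7e-05, 0.22 with an estimated correlation), lost the call with a common total (0.54). Cell cycle genes, which had not passed camera for TGFB1, instead went upward (median 0.37) with 0 called (0.00012, 0.62). Their list call was lost with fry (0.32). These counts depended on the scaling. A common total left 0 heat shock genes lower and 1 higher, 4 contractile genes lower, 7 YAP and TAZ targets lower and 4 higher, 8 immediate early genes lower and 2 of the metallothionein list, and 4 cell cycle genes higher. Median centring gave 15 heat shock genes, 15 contractile genes, 15 chaperones and 12 proteasome subunits lower.

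Of the 2937 genes raised by TGFB1, 1876 were lower when celastrol was added. Both comparisons use the TGFB1 libraries, with opposite sign, which cannot be split with 2 per group and which favours such an overlap without any effect. In 50 simulated sets of unchanged groups the 2 sets of changes correlated at -0.56, further from 0 than the observed -0.33, with a covariance of -0.0452 against an observed -0.418. The simulated sets had nearly no calls, so they give no reference for the number of genes. Without control replicate 2 the number was 1124. Of the same 2937 genes, 526 were higher still with celastrol.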

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

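The tests of explanations in this part were chosen after the result was seen, and the interaction test before. The interaction was past the threshold for the genes named here by the rule fixed before the data were examined. The TGFB1 change was more positive with celastrol for KIT by 4.10, TEX41 by 3.19, ARHGAP28 by 3.19, EVI2A by 3.19 and ADAMTS1 by 3.15 on the log2 scale. It was more negative for EGR2 (-7.55), COMP (-5.61), ANGPTL4 (-5.51), GPRIN3 (-5.28) and LIF (-5.07). The call of TEX41 was lost without celastrol replicate 2 or either library with both agents (adjusted p = 0.0845, 0.07 and 0.088), and that of GPRIN3 without either celastrol library or replicate 2 with both agents (0.0694, 0.0621 and 0.0615). Without a variance trend the TEX41 and GPRIN3 calls were lost (0.0584 and 0.0682).

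The pattern behind these is a TGFB1 change near 0 with celastrol, with a slope of 0.03 over 5364 genes. The tables argue against TGFB1 missing from the libraries labelled with both agents, since 7 of 31 early response genes were higher there than with celastrol alone, adjusted over the list alone, and 0 were lower. The list test of that response was not past the threshold with fry (0.31), so this rests on the 7 genes. Adjusted over all genes, 1 of them, JUNB, passed with voom weights (0.0405), a setting added later, but not in the main limma fit (0.23). The authors' scaling could not be tested by other scalings, since 1 factor per library leaves a slope across genes nearly unchanged (0.03 at most). Celastrol alone having already reached the TGFB1 level may account for part of it: 270 of 714 genes raised at least 2-fold by TGFB1 (37.8%) had a celastrol mean at or above the TGFB1 mean, which decides neither way for the set. An effect of celastrol on the response to TGFB1 remains an open hypothesis.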

How the results depend on the processing

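Settings were planned before the data were examined, apart from voom weights and the common-total, TMM and median scalings of the slope. Count models with edgeR and DESeq2 were planned and not run, because whole reads were not recovered. Genes changed by TGFB1 were 1747 with a fold of at least 2 and 1684 with the 4 compared libraries only. Genes changed by celastrol with TGFB1 were 9344 with a mean of at least 50 and 7864 with the fold threshold. Those changed by celastrol without TGFB1 were 7932 and 6878. Of the 9344 and 7932 genes, 4053 and 3761 were higher, so at that mean more genes were lower than higher in both comparisons. Genes changed by TGFB1 with celastrol were 0 with a pseudocount of 0.1, no filter, TMM or median centring, 1 with a pseudocount of 10, a mean of at least 50, no trend, the robust fit, the replicate block or 4 libraries, and 4 with voom weights. Genes with an interaction were 1245 without a trend and 945 with the fold threshold. For genes near 0 without celastrol, limits of 2 or 10 for such a gene and of 100 or 1000 for its neighbour, in place of 5 and 300 (taken after a first limit of 500), gave near-to-far ratios from 1.68 to 1.86, and levels not divided by length gave 1.41. Lists called were 0 with an estimated correlation in all 5 comparisons, and with fry 20 for celastrol with TGFB1, 17 without it and 0 for TGFB1 with celastrol. The slope was 0.042 with a pseudocount of 10, and 239 genes raised by TGFB1 fell with celastrol at a fold of at least 2.

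Leaving out 1 library at a time assumes that the lone library of a group varies like the others. It gave 3248 to 4757 genes changed by TGFB1, 12172 to 14214 by celastrol with TGFB1, 10051 to 13222 without TGFB1, 0 to 0 by TGFB1 with celastrol, and 1189 to 2715 with an interaction. Lists called were 8 to 12, 10 to 11, 6 to 11, 6 to 9 and 11 to 15 in the same order. The slope was 0.018 to 0.04, and genes raised by TGFB1 that fell with celastrol 1124 to 1711.

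For TGFB1 against control, a common total turned the log2 change of CD68 (-0.151), COL1A2 (-0.08), KRT10 (-0.105), MT-CO1 (-0.031), MT-CYB (-0.026), SLC30A1 (-0.071), YAP1 (-0.166). For celastrol without TGFB1, a common total turned the log2 change of CCN2 (-0.053). For celastrol with TGFB1, a common total turned the log2 change of CCN1 (0.141), PMEL (0.144), YAP1 (0.137). For the interaction, a common total turned the log2 change of COL3A1 (0.166), DDIT3 (0.222), YAP1 (0.129). For TGFB1 against control, voom weights turned the log2 change of CD68 (-0.007). For celastrol without TGFB1, voom weights turned the log2 change of ACTA2 (0.051). For celastrol with TGFB1, voom weights turned the log2 change of PMEL (0.018). For TGFB1 against control, median centring turned the log2 change of COL3A1 (0.051). For celastrol without TGFB1, median centring turned the log2 change of CCN2 (-0.144), DSP (-0.043), YAP1 (-0.083). For celastrol with TGFB1, median centring turned the log2 change of SLC30A1 (-0.225). For the interaction, median centring turned the log2 change of DNAJB1 (-0.066). For celastrol without TGFB1, TMM scaling turned the log2 change of CCN2 (-0.024). Across the libraries left out, changes that turned sign or reached 0 in TGFB1 against control ran over ACTA2 -0.113 to 0.934, CD163 0 to 1.79, CD68 -0.209 to 0.356, COL3A1 -0.142 to 0.003, DDIT3 -0.342 to 0.056, MLANA 0 to 1.156, PECAM1 -0.678 to 0, PMEL -0.022 to 0.46, POSTN -0.065 to 0.994, PTPRC -1.093 to 0.251, TYRP1 -1.13 to 0.635, VWF -0.699 to 0.167. With 1 library left out at a time, changes that turned sign or reached 0 in TGFB1 with celastrol ran over ACTA2 -0.726 to 0.186, COL1A1 -0.344 to 0.03, DDIT3 -0.386 to 0.07, DNAJB1 -0.264 to 0.035, FN1 -0.092 to 0.122, HSPA1A -0.161 to 0.197, NOX4 -0.094 to 0.415, POSTN -0.458 to 0.404. Across the libraries left out, changes that turned sign or reached 0 in celastrol without TGFB1 ran over ACTA2 -0.567 to 0.481, CCN2 -0.113 to 0.167, PMEL -0.098 to 0.973, POSTN -0.589 to 0.461. With 1 library left out at a time, changes that turned sign or reached 0 in celastrol with TGFB1 ran over CCN1 -0.063 to 0.029, PMEL -0.241 to 0.241, SLC30A1 -0.011 to 0.137, YAP1 -0.05 to 0.009. Across the libraries left out, changes that turned sign or reached 0 in the interaction ran over COL3A1 -0.182 to 0.039, DDIT3 -0.243 to 0.213, DNAJB1 -0.098 to 0.201, HSPA1A 0 to 0.358, POSTN -1.021 to 0.038. For TGFB1 against control, fry turned the direction of matrix proteases (adjusted p = 0.03). For celastrol with TGFB1, fry turned the direction of cell cycle (adjusted p = 0.83), fibroblast identity (adjusted p = 0.58). For celastrol without TGFB1, fry turned the direction of endoplasmic reticulum chaperones (adjusted p = 0.41). For TGFB1 against control, the replicate block turned the direction of matrix proteases (adjusted p = 0.96). For TGFB1 against control, a common total turned the direction of ATF4 and integrated stress response (adjusted p = 0.83), cholesterol synthesis (adjusted p = 0.68). For celastrol with TGFB1, a common total turned the direction of cell cycle (adjusted p = 0.92). For celastrol without TGFB1, a common total turned the direction of p53 targets (adjusted p = 0.91), fibroblast identity (adjusted p = 0.72). With 1 library left out at a time, adjusted p of lists whose direction turned in TGFB1 against control ran over endothelial 0.42 to 0.8, ATF4 and integrated stress response 0.028 to 0.81. Across the libraries left out, adjusted p of lists whose direction turned in celastrol with TGFB1 ran over cell cycle 0.38 to 0.98. With 1 library left out at a time, adjusted p of lists whose direction turned in celastrol without TGFB1 ran over fibroblast identity 0.78 to 0.98, p53 targets 0.58 to 0.93. For TGFB1 with celastrol, adjusted p of the cell cycle list ran from 6.5e-27 to 0.98 and its direction turned. None of the genes that turned sign or reached 0 had passed the threshold, and of the lists only that one had.

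The 2 replicate numbers are not established as pairs, and the labels of the celastrol library taken as replicate 2 also carry the number 3. Deviations from the group mean correlated between groups by 0.171 to 0.233 across 14739 genes. A replicate block gave 6542 genes for TGFB1, 15312 and 13548 for celastrol with and without it, 1 for TGFB1 with celastrol and 3665 for the interaction. Among other genes it newly called ACTA2 and POSTN for TGFB1 and for celastrol with TGFB1, and in the interaction ACTA2 (0.0156), COL1A2 (0.0427) and POSTN (0.0254). It ended the TGFB early response list call for celastrol without TGFB1 (0.064), and added cell cycle for TGFB1 (0.022) and NRF2 targets for celastrol without it (0.027). Lists called with the block were 15 for the interaction, against 11, and 10 for TGFB1 with celastrol, against 9. The cause was not tested.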

Other observations

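The tests of explanations in this part were chosen after the patterns were seen, apart from the correlation with the level of the upstream neighbour in the libraries with celastrol. Genes that TGFB1 lowered were mostly higher when celastrol was added. Of 2427 such genes, 1829 were higher with celastrol and TGFB1 than with TGFB1 alone. The TGFB1 libraries enter both comparisons with opposite sign, which favours such a count without any effect. The inhibitory SMAD6 was at -2.46 with TGFB1 and 2.15 when celastrol was added. Celastrol raised 6594 genes and lowered 3672 both with and without TGFB1, against 2898 and 1263 for independent lists. These comparisons share no library. The table leaves out genes under 11 estimated reads in every library, however. Most genes near 0 without celastrol must then be higher with it, which favours the count of raised genes. In the interaction, collagen and matrix genes had 25 of 36 lower (camera adjusted p = 6.8e-16, adjusted p = 0.20 with an estimated correlation) and interferon response genes 4 of 20 higher (0.0075, 0.22 with an estimated correlation). Both lists had moved the other way with TGFB1, and the shared TGFB1 and control libraries favour such a reversal.

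The first pattern is that 4835 genes had a mean under 5 normalized reads in the 4 libraries without celastrol, against 774 with a mean under 5 in the 4 with it. The table holds only genes that reach 11 estimated reads in some library, so most genes low in 1 set must be higher in the other, and the pattern is the difference between these numbers. Of the 4835, 215 reached a mean of 100 with celastrol. Several of the largest celastrol rises, such as NEB, C9, CD160 and MSTN, belong to this set. The nearest expressed gene upstream on the same strand lay 54497 bases from NEB, 1087465 from C9 and 48821 from CD160. The result below for genes within 10 kb of such a gene therefore does not cover NEB, C9 or CD160.

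Greater depth does not account for this first pattern. Over all genes of the table, a library without celastrol was deeper than one with it in 6 pairs. In each pair the deeper library had 9.24 to 18.07 times as many genes under 1 read. The tests by distance used 3220 of the 4835 genes and say nothing of the others. Left out were genes without an exon length and those overlapping an expressed gene, meaning one with a mean of at least 300 without celastrol. Per kb of exon, the median level was 1.8 times as high within 10 kb downstream of an expressed gene on the same strand (297 genes) as beyond 500 kb (744 genes), with a bootstrap interval from 1.47 to 2.15, against 1.21, 1.03 and 0.76 in the other 3 orientations; this argues against genomic DNA for the excess of the near genes, but not for the level they share with the far ones. Levels per kb were already higher near such a gene without celastrol (1.71 times, against 3.21, 1.5 and 1.41 times in the other orientations), so only the gain with celastrol bears on this; its ratio was 1.89, against 1.18, 0.94 and 0.77. Read-through from the upstream gene is a candidate source for the near genes. Across 1009 genes within 50 kb, the level per kb with celastrol correlated with that of the upstream neighbour (Spearman rho = 0.271). It correlated less with that of a downstream one (0.043, 608 genes), although genes are not independent. Without celastrol the value for the upstream neighbour was -0.059. These genes were chosen for a mean under 5 normalized reads without celastrol, which leaves little range for a correlation. The value of -0.059 therefore cannot tell whether the correlation arose with celastrol. For the 744 far genes, read-through and genomic DNA cannot be told apart, because the limit of 11 reads fixes both their median with celastrol (12.1) and the rise of their level with exon length (1.49 times from the 25% with the shortest to the 25% with the longest), and the use of strand in counting is not given.

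The second pattern is the fall of mitochondrially encoded transcripts with celastrol, which took their share of normalized reads from between 0.55% and 0.65% to between 0.13% and 0.17%. A single common loss of mitochondrial RNA is argued against by the range of the 13 log2 changes, which was 3.8, from -0.68 for MT-ND5 to -4.48 for MT-CO3 (celastrol with TGFB1), and 3.08 without MT-ND5. The MT-ND5 change was -0.34 without TGFB1 with celastrol replicate 2 (adjusted p = 0.163), and its call was also lost without TGFB replicate 1 (0.111), with a common total (0.0611), without a trend (0.0755) and with the 4 compared libraries (0.0542). Reads shifting to nuclear copies are argued against by the summed gain of 35 mitochondrial pseudogenes, which was 0.58% of the summed loss. A response of these transcripts to celastrol remains a hypothesis, and transcript-specific loss during library preparation was not tested.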
